A study of Sus scrofa with 10 samples.

How the data were processed

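Bulk RNA was sequenced from the right ventricle of 10 pigs, 5 with CTEPH (chronic thromboembolic pulmonary hypertension) and 5 Sham controls, with 1 library per pig, per the labels. The libraries are named s1 to s10 after the labels. Libraries s1, s3, s4, s5 and s9 are CTEPH and libraries s2, s6, s7, s8 and s10 are Sham. Each number occurs once, so no library is paired with another, and no batch, sex, age or time after surgery is given in the sources used here. The molecule is given as polyA RNA, while the extraction protocol names an Illumina stranded kit for total RNA, so whether polyadenylated RNA was selected stays open. The submitters' processing notes name bcl2fastq 2.18.12, cutadapt 1.15, FastQC 0.11.5, featureCounts (version not given), edgeR 3.36.0, limma 3.50.0 and the pig genome build Sscrofa11.1. The aligner, the gene annotation, the strand setting of the counting and the filter on low genes are not given in the sources used here.

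The deposited values are on a log2 scale, 1 value for each of 15638 Ensembl pig genes in each library. The libraries hold nearly the same distribution of deposited values, with medians of 9.305 to 9.308, as quantile normalization leaves behind where values are tied. The low values follow from whole counts: each equals the quantile mean over the 10 libraries of log2(count + 1), with counts known up to a common factor of 2. Below a log2 value of 9.48, 82505 values (52.8% of the table) could be read back as whole counts with an error of at most 5.0e-10, against a tolerance of 1e-06, and 6763 genes had such counts in all 10 libraries. Total counts per library could not be computed, because the higher values do not give back their counts. Relative depth was taken as the median ratio of a library's counts to the geometric mean over libraries, over genes recovered in all 10 libraries with at least 5 counts in each, scaled to a geometric mean of 1. Quantile normalization brings all libraries to nearly 1 distribution, so a change shared by most genes could not appear in these values, and fold changes of low genes are compressed by the 1 added before the logarithm.

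Gene symbols came from a table of Ensembl identifiers, which matched 12378 of the genes and left 3260 without a symbol. Coordinates came from the RefSeq gene table of Sscrofa11.1, matched by symbol, and are counted from 1. MYH7 had no symbol match and is not analysed here. Genes with near-identical copies, such as MYH6 and members of gene families in tandem, are uncertain where reads could be shared, because the treatment of shared reads is not given in the sources used here.

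The groups were compared with limma 3.58.1 in R 4.3.3, with moderated variances that follow an intensity trend, no covariate and a two-sided test. P-values were adjusted with the Benjamini-Hochberg method over all genes, and genes at an adjusted p under 0.05 are called rising or falling in CTEPH. Fold changes are CTEPH minus Sham on the log2 scale and are given with the standard error (SE) of the fit. Before the data were examined, 43 gene lists were fixed, on load responses, matrix, metabolism, signalling and the cell types that a ventricular biopsy can hold. The 40 lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The main test of fry asks whether the genes of a list move in 1 direction on balance and its mixed test whether they change in either direction, and neither compares a list with other genes. A list's level in a library is the mean over its genes of the log2 value minus the gene's mean over the 10 libraries, compared between groups with a two-sided exact permutation test over the 252 assignments of libraries to groups, for which 0.00794 is the smallest possible p. Principal components were taken from the 1000 most variable genes.

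The named genes follow a rule fixed at the same time. It takes the 12 largest rises and the 12 largest falls among called genes with a symbol whose groups do not overlap. It adds up to 4 genes with the smallest p from each list and a set of 14 genes of load, matrix, calcium handling, vessels and fuel use, of which 13 were measured. The rule named 195 genes, of which 1 is left out and not reported here. The alternatives were recomputed for 160 of them, leaving out genes that only a list named and that had an unadjusted p of 0.05 or more, the sex-linked genes excepted. Names outside this rule are marked as chosen after their values were seen.

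The test was tried on simulated data before use, with log2 values drawn for 15638 genes from the real gene means and residual spreads, 200 of them changed, and then quantile-normalized. In the simulated comparison of CTEPH against Sham, 51.5% of genes changed by 1 on the log2 scale were recovered, 95.0% of those changed by 2 and 99.0% of those changed by 3. False calls made up 7.21%, 6.40% and 5.26% of calls in these 3 runs. The noise was drawn independently for each gene with the same spread in both groups, and the lowest genes were not changed. These rates may therefore not hold for the real libraries, where genes are correlated and CTEPH libraries spread more widely. The recovery of counts was tested on simulated counts as well.

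The alternatives were no intensity trend, robust empirical Bayes, other scalings, a filter on low genes, library weights, a fold threshold, 1 surrogate variable and leaving out each library in turn. The surrogate variable was estimated with the iteratively reweighted algorithm written out in R. Relative depth as a covariate and voom on the recovered counts were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.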

Results

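Right ventricular expression was measured in 5 pigs with chronic thromboembolic pulmonary hypertension (CTEPH), in which obstructed pulmonary arteries load the right ventricle with pressure, and in 5 Sham pigs. Each pig gave 1 library, with a log2 value for every gene of the table. Relative depth, read from the recovered low counts, ranged from 0.724 in CTEPH library s9 to 1.57 in CTEPH library s4. It was 1.05 ± 0.317 in CTEPH and 1.02 ± 0.320 in Sham (SD, n = 5 each; two-sided exact permutation p = 0.857). Between 4 and 33 genes per library had a count of 0. Sham libraries correlated with each other at Pearson r of 0.959 to 0.972 across genes, CTEPH libraries at 0.943 to 0.964, and libraries of different groups at 0.927 to 0.958, where genes are not independent replicates.

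The design compares the right ventricle of CTEPH pigs with that of Sham pigs and asks which transcripts differ in the remodelled ventricle. The CTEPH ventricles carried far more transcript of the cell division machinery and of the stretch hormone gene NPPB. A few collagen-modifying (2 of 18), matrix (4 of 32) and macrophage genes (4 of 24) were higher. A few endothelial (3 of 24) and neurohormonal genes (3 of 27) were lower, and each of these lost its call in some refits without 1 library. Among the higher genes of these lists LOXL1, CTHRC1, LYZ and TREM2 did too, and the others kept their calls. Of the genes tested, 723 (4.62%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 443 higher and 280 lower in CTEPH, and 3181 had an unadjusted p under 0.05. The rises were larger than the falls: 156 genes were at least 4-fold higher and 20 at least 4-fold lower, and the median log2 fold change was 1.51 among rising and -0.97 among falling genes. The groups did not overlap for 1027 genes (6.57%, where chance gives 0.794%), 581 of them called. Leaving out Sham library s2, s6, s7 or s10 lowered the count of called genes to 475, 425, 462 and 417, and leaving out CTEPH library s4 or s5 lowered it to 401 and 475 (limma, Benjamini-Hochberg). Without CTEPH library s3 or Sham library s8 the count was 502 and 485. Leaving out CTEPH library s1 or s9 instead raised it, to 961 each. Falling genes numbered 170, 117, 146 and 136 without s2, s6, s7 and s10, 131 and 167 without s4 and s5, and 171 and 155 without s3 and s8, and rising genes 270 without s4 and 281 without s10. Library weights gave 1269 genes, 722 higher and 547 lower, testing against a 1.5-fold change gave 127, 121 higher and 6 lower, and dropping the lowest 25% of genes left 273 higher.

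The groups separated on the first principal component, which held 35.6% of the variance of the 1000 most variable genes. Its score was 26.6 ± 13.6 in CTEPH and -26.6 ± 0.822 in Sham (SD, n = 5 each; two-sided exact permutation p = 0.00794, the smallest that this design allows). The CTEPH libraries were spread widely, with s9 at 10.4 and s1 at 15.2 nearest to Sham and s4 at 43.3 farthest. The second component held 13.2% of the variance.

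**Figure D1:**
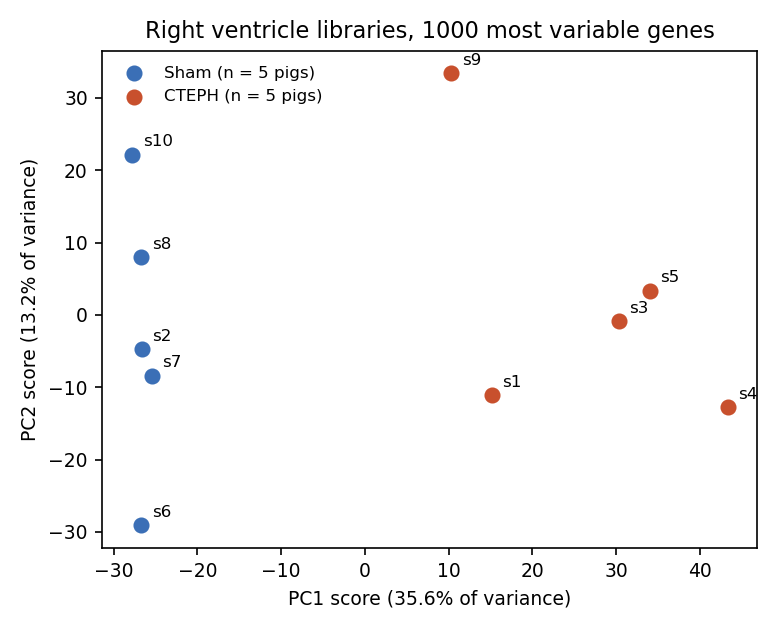
Scores of the 10 right ventricle libraries on the first component (horizontal, 35.6% of variance) and the second component (vertical, 13.2% of variance), 1 point per pig, Sham in blue and CTEPH in red. The Sham libraries lie close together on the horizontal axis around -26.6, while the CTEPH libraries run from 10.4 to 43.3.

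NPPB, which encodes the B-type natriuretic peptide released by stretched cardiomyocytes, had the largest rise among the named genes. Its log2 value was 13.07 ± 2.03 in CTEPH and 6.49 ± 1.31 in Sham (SD, n = 5 each), a log2 fold change of 6.57 ± 0.85 (SE; adjusted p = 7.6e-04, limma with Benjamini-Hochberg). The gene lies on chromosome 6 from 71930374 to 71931843 of Sscrofa11.1, and all 5 CTEPH libraries exceeded every Sham library. In the natriuretic and stretch list, 6 of 16 measured genes rose and 0 fell, and 12 rose when adjusted over the list alone (limma, Benjamini-Hochberg). The rising genes included ANKRD2 (log2 fold change 4.08 ± 0.59), the actin-binding XIRP2 (2.17 ± 0.46), the calcineurin regulator RCAN1 (1.87 ± 0.38) and the titin-associated ANKRD1 (1.46 ± 0.37). NPPA, the atrial natriuretic peptide gene that neighbours NPPB, was at 13.63 ± 1.39 in CTEPH and 11.80 ± 1.24 in Sham, and its difference of 1.83 did not pass (adjusted p = 0.137, limma with Benjamini-Hochberg). The list ranked above other genes (camera adjusted p = 1.6e-08, Benjamini-Hochberg), with an adjusted p = 0.618 with an estimated correlation. ANKRD1 lost its call in 8 of the 10 refits that each left out 1 library, with an adjusted p of up to 0.108 (limma, Benjamini-Hochberg).

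Cell division genes rose together. All 26 measured genes of the proliferation list rose and 0 fell, also when adjusted over the list alone (limma, Benjamini-Hochberg), with a median log2 fold change of 2.97. The mitotic ubiquitin-conjugating enzyme UBE2C (chromosome 17, 48018403 to 48021542) rose by 4.66 ± 0.39 on the log2 scale, from 4.58 ± 0.74 in Sham to 9.24 ± 0.64 in CTEPH (SD, n = 5 each; adjusted p = 7.8e-05, limma with Benjamini-Hochberg). The mitotic kinesin KIF20A rose by 4.27 ± 0.37, the spindle checkpoint kinase BUB1 by 3.98 ± 0.34 and the replication helicase subunit MCM2 (chromosome 13, 72630378 to 72651270) by 2.68 ± 0.25. Other genes among the 12 largest rises, which are on no list, were CDCA3 (4.82 ± 0.43), the centrosomal kinase NEK2 (4.52 ± 0.50), KIF14 (4.36 ± 0.51), SHCBP1 (4.23 ± 0.53), and the kinetochore and spindle genes NDC80 (4.16 ± 0.52), CENPT (4.10 ± 0.39) and DLGAP5 (4.09 ± 0.42). In each of these genes all 5 CTEPH libraries lay above every Sham library, which the naming rule requires of the 12 largest rises. The list ranked above other genes (camera adjusted p = 1.6e-44, Benjamini-Hochberg), with an adjusted p = 0.189 with an estimated correlation. By fry its adjusted p was 5.8e-04 (Benjamini-Hochberg).

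DNAAF6 and TESMIN completed the largest rises, both from very low Sham counts. DNAAF6, a factor of axonemal dynein assembly, had recovered counts of at least 28 in each CTEPH library and of 0 to 3 in the Sham libraries, with a log2 fold change of 5.04 ± 0.54 (adjusted p = 1.6e-04, limma with Benjamini-Hochberg). TESMIN, known from the testis, had 179 counts over the CTEPH libraries and 2 over the Sham libraries, a depth-scaled ratio of 86.6 with a 95% exact counting interval of 23.6 to 720.4. The interval covers counting error only.

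A few matrix genes rose. In the list of fibrillar collagens and matrix, 4 of 32 measured genes rose and 0 fell, and 9 rose when adjusted over the list alone (limma, Benjamini-Hochberg). The rising genes were COL8A1 (chromosome 13, 159216138 to 159374718; log2 fold change 1.80 ± 0.23), COL12A1 (1.57 ± 0.31), the small proteoglycan ASPN (1.21 ± 0.24) and CTHRC1 (2.54 ± 0.66). The main fibrillar collagen genes COL1A1 and COL3A1 differed by 0.38 ± 0.30 and -0.05 ± 0.22, and the matricellular POSTN by 0.70 ± 0.20, none of which passed (adjusted p = 0.521, 0.925 and 0.0708, limma with Benjamini-Hochberg). The lysyl oxidase family genes LOXL2 (1.39 ± 0.25) and LOXL1 (2.21 ± 0.48) were the 2 rising genes among 18 measured genes of collagen processing and crosslinking, of which 0 fell and 5 rose when adjusted over the list alone. Among 18 fibroblast and myofibroblast genes, CCN2 rose (2.33 ± 0.50), 0 fell, and 2 rose when adjusted over the list alone. The 3 lists ranked above other genes, at camera adjusted p = 0.00129, 0.00464 and 0.00659 (Benjamini-Hochberg). With an estimated correlation their adjusted p = 0.773, 0.734 and 0.734. List levels differed between CTEPH pigs: the fibrillar collagen and matrix level was 1.06 in s4, 0.54 in s3 and 0.49 in s5, but -0.37 in s1 and -0.28 in s9, within the Sham range of -0.51 to -0.05.

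A few basement membrane and protease genes were called. NID2 (1.13 ± 0.17) and COL4A5 (1.66 ± 0.32) rose among 15 basement membrane genes, 0 fell, and 4 rose and 1 fell when adjusted over the list alone (limma, Benjamini-Hochberg). Among 20 matrix proteases and inhibitors 1 rose and 2 fell: MMP11 (chromosome 14, 49907684 to 49917494) and TIMP3 fell by 2.07 ± 0.31 and 0.74 ± 0.13, and 6 rose and 2 fell when adjusted over the list alone. Both lists were uncalled (camera adjusted p = 0.227 and 0.237, Benjamini-Hochberg). CTHRC1, CCN2 and LOXL1 lost their calls in 8, 2 and 2 of the 10 refits without 1 library, and CTHRC1 also with voom on recovered counts (limma adjusted p = 0.0744, Benjamini-Hochberg).

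Some macrophage genes rose. Of 24 measured macrophage and monocyte genes, 4 rose and 0 fell, and 7 rose when adjusted over the list alone (limma, Benjamini-Hochberg): the lysosomal protease LGMN (0.85 ± 0.16), osteopontin gene SPP1 (2.30 ± 0.47), lysozyme gene LYZ (2.38 ± 0.55) and the lipid receptor TREM2 (2.69 ± 0.65) passed over all genes. TREM2 counts were low, at 6 to 76 in the CTEPH libraries and 1 to 7 in the Sham libraries. The list ranked above other genes (camera adjusted p = 3.6e-05, Benjamini-Hochberg; median log2 fold change 0.43), with an adjusted p = 0.70 with an estimated correlation and 0.174 by fry. Of the lymphocyte lists, 0 of 19 T and NK lymphocyte genes and 0 of 8 B and plasma cell genes passed by limma, with 0 at an unadjusted p under 0.05 in either list and 0 adjusted over the list alone, median log2 fold changes of 0.02 and 0.41 and camera adjusted p = 0.739 and 0.433 (Benjamini-Hochberg). Among 5 neutrophil and mast cell genes 0 passed by limma, 3 had an unadjusted p under 0.05, and 1, MS4A2 (-0.81 ± 0.25), was lower when adjusted over the list alone (camera adjusted p = 0.897, Benjamini-Hochberg). The adhesion molecule gene VCAM1 fell by 0.89 ± 0.17, the only called gene of 21 on the list of inflammatory cytokines and adhesion, also when adjusted over the list alone, and CFD, complement factor D, fell by 1.26 ± 0.30 as the only called gene of 17 complement genes, also when adjusted over the list alone (camera adjusted p = 0.497 and 0.806, Benjamini-Hochberg). LYZ, TREM2 and CFD lost their calls in 5, 7 and 6 of the 10 refits without 1 library, and TREM2 also with voom on recovered counts (limma adjusted p = 0.0891, Benjamini-Hochberg).

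No interferon response gene passed, and the spread between pigs of each group was wide. Of 30 measured genes, 0 passed by limma, 1 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone; the median log2 fold change was -0.41 and RSAD2 was at -1.46 ± 0.53 (adjusted p = 0.143, limma with Benjamini-Hochberg). List levels ranged from -1.03 in s2 to 0.81 in s8 within Sham and from -0.63 in s5 to 0.71 in s1 within CTEPH. The list ranked below other genes (camera adjusted p = 0.0311, Benjamini-Hochberg), with an adjusted p = 0.774 with an estimated correlation and 0.517 by fry. Its level did not differ detectably between groups (two-sided exact permutation p = 0.405). The call ended when CTEPH library s3, s4 or s5 was left out (camera adjusted p = 0.103, 0.0892 and 0.149, Benjamini-Hochberg) or Sham library s6, s8 or s10 (0.177, 0.226 and 0.204).

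A few endothelial genes fell. The angiopoietin receptor TEK fell by 0.78 ± 0.17, the water channel AQP1 by 0.60 ± 0.14 and the VEGF receptor FLT1 by 0.94 ± 0.22, 3 of 24 measured endothelial genes, with 0 rising and the same count adjusted over the list alone (limma, Benjamini-Hochberg). KDR, the main VEGF receptor, was at -0.36 ± 0.22 and the ligand VEGFA at -0.38 ± 0.23, neither of which passed (adjusted p = 0.389 and 0.392, limma with Benjamini-Hochberg). The list ranked below other genes (camera adjusted p = 7.0e-04, Benjamini-Hochberg), with an adjusted p = 0.734 with an estimated correlation and 0.194 by fry. Its level in Sham libraries s2 (-0.17) and s10 (-0.09) lay within the CTEPH range of -0.24 to -0.018 (two-sided exact permutation p = 0.0556). Among 29 angiogenic and hypoxia genes, the hypoxia-inducible factor EPAS1 fell by 0.68 ± 0.15 and ESM1 rose by 1.38 ± 0.34, with 1 rising and 3 falling when adjusted over the list alone (camera adjusted p = 0.460, Benjamini-Hochberg). RELN fell by 1.40 ± 0.30 among 8 lymphatic endothelial genes, of which 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0631, Benjamini-Hochberg). TEK, AQP1, FLT1, EPAS1, ESM1 and RELN lost their calls in 5, 7, 5, 1, 7 and 2 of the 10 refits without 1 library.

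**Figure D2:**
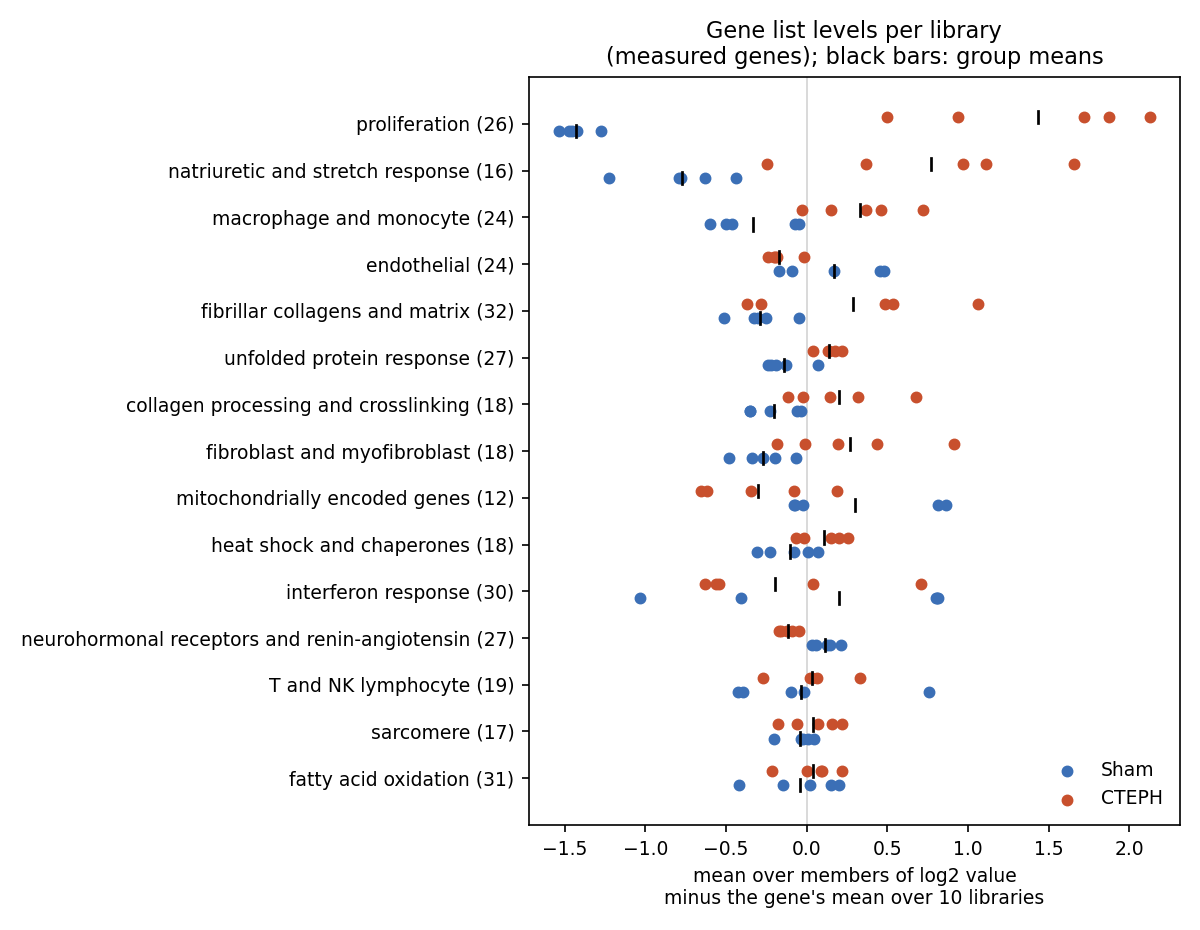
List levels (horizontal, mean over measured genes of the log2 value minus the gene's mean over 10 libraries) for the 12 called lists and 3 uncalled lists, 1 point per pig, Sham in blue and CTEPH in red, black bars for group means and the number of measured genes in parentheses. The proliferation level lies between 0.50 and 2.13 in CTEPH and between -1.54 and -1.27 in Sham, while most other lists overlap between groups.

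Sarcomere and electrical genes changed in few members. MYL2, the ventricular regulatory light chain (chromosome 14, 32205953 to 32213848), rose by 0.99 ± 0.21 to 19.81 ± 0.25 in CTEPH from 18.83 ± 0.25 in Sham (SD, n = 5 each; adjusted p = 0.0173, limma with Benjamini-Hochberg), and MYOZ2 rose by 0.69 ± 0.16. They were the 2 called genes of 17 sarcomere genes, of which 3 rose when adjusted over the list alone (camera adjusted p = 0.433, Benjamini-Hochberg). The skeletal actin gene ACTA1, part of the fetal program, was at 1.19 ± 0.38 and the fast myosin gene MYH6 at 0.16 ± 0.31, neither passing (adjusted p = 0.0936 and 0.822, limma with Benjamini-Hochberg). Slow skeletal troponin TNNT1 rose by 3.05 ± 0.46, the only called gene of 11 skeletal muscle genes, of which 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.806, Benjamini-Hochberg). KCND3, which carries the transient outward potassium current (chromosome 4, 108394687 to 108621514), fell by 2.0 ± 0.36 and KCNA5, of the ultrarapid current, rose by 0.77 ± 0.20 among 17 ion channel and gap junction genes, of which 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.373, Benjamini-Hochberg). By limma 0 of 20 calcium handling genes passed, with 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.991, Benjamini-Hochberg), and the calcium pump ATP2A2 and its inhibitor PLN were at -0.06 ± 0.19 and 0.01 ± 0.14. MYL2, MYOZ2 and KCNA5 lost their calls in 1, 6 and 8 of the 10 refits without 1 library.

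On the lists of energy metabolism no nuclear gene passed over all genes. By limma 0 of 31 fatty acid oxidation genes, 0 of 58 oxidative phosphorylation genes, 0 of 26 pyruvate dehydrogenase and TCA cycle genes and 0 of 19 genes of branched-chain amino acid and ketone use passed, with 0 adjusted over each list alone. At an unadjusted p under 0.05 there were 5, 1, 1 and 2 genes, and the lists had camera adjusted p = 0.806, 0.824, 0.679 and 0.679 (Benjamini-Hochberg). PDK4, which restrains pyruvate oxidation, was at 14.41 ± 2.03 in CTEPH and 12.78 ± 0.77 in Sham, and its difference of 1.63 did not pass (adjusted p = 0.254, limma with Benjamini-Hochberg). Among 23 genes of glycolysis and glucose uptake, 0 passed over all genes by limma and 9 had an unadjusted p under 0.05, while adjusted over the list alone LDHA (1.07 ± 0.31) and PGAM1 (1.04 ± 0.31) were higher and the insulin-responsive transporter SLC2A4 (-0.52 ± 0.14) lower (camera adjusted p = 0.0619, Benjamini-Hochberg). All 12 measured mitochondrially encoded genes had negative fold changes, with a median of -0.41 and ND1 at -1.16 ± 0.38, but 0 passed, also when adjusted over the list alone, and 3 had an unadjusted p under 0.05 (limma). The list ranked below other genes (camera adjusted p = 0.0102, Benjamini-Hochberg), with an adjusted p = 0.773 with an estimated correlation, and the call ended without CTEPH library s5 (camera adjusted p = 0.0529, Benjamini-Hochberg). Its level was 0.81 in s2 and 0.86 in s8 and between -0.08 and -0.02 in the other 3 Sham libraries.

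Genes of the endoplasmic reticulum stress response rose in part. The chaperones DNAJB9 (0.83 ± 0.15) and DNAJB11 (0.65 ± 0.15) and the serine synthesis enzyme PHGDH (1.98 ± 0.40) rose, 3 of 27 measured genes of the unfolded protein response list, with 0 falling and 4 rising when adjusted over the list alone (limma, Benjamini-Hochberg). The list ranked above other genes (camera adjusted p = 0.00464, Benjamini-Hochberg), with an adjusted p = 0.70 with an estimated correlation. Of 18 heat shock and chaperone genes, 0 passed over all genes by limma, 5 had an unadjusted p under 0.05 and 4 were higher when adjusted over the list alone, among them HSPH1 (0.79 ± 0.21) and HSPA4 (0.63 ± 0.17), with a list call at camera adjusted p = 0.0204 (Benjamini-Hochberg) and an adjusted p = 0.734 with an estimated correlation. That call ended without CTEPH library s1 or Sham library s8 (camera adjusted p = 0.0566 and 0.0575, Benjamini-Hochberg), and DNAJB11 lost its call in 6 of the 10 refits without 1 library.

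A few neurohormonal genes fell. The angiotensin-converting enzyme gene ACE fell by 1.44 ± 0.37, the adrenergic receptor gene ADRA2C by 0.85 ± 0.18 and the phosphodiesterase gene PDE2A by 0.60 ± 0.15, 3 of 27 measured genes, with 0 rising and 4 falling when adjusted over the list alone (limma, Benjamini-Hochberg). The list ranked below other genes (camera adjusted p = 0.0359, Benjamini-Hochberg), with an adjusted p = 0.421 with an estimated correlation. By fry, which tests the list's own direction, its adjusted p was 6.9e-04 (Benjamini-Hochberg). Among 26 TGF-beta and BMP signalling genes the ligand TGFB2 rose (0.95 ± 0.24), while the activin antagonist FST and the receptor ACVRL1 fell by 1.83 ± 0.39 and 0.77 ± 0.18, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.433, Benjamini-Hochberg). IGFBP5, which binds insulin-like growth factors, fell by 1.36 ± 0.22, the only called gene of 25 growth and hypertrophy signalling genes, of which 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.399, Benjamini-Hochberg). The neurohormonal list lost its call without Sham library s2 or CTEPH library s3 (camera adjusted p = 0.0598 and 0.0599, Benjamini-Hochberg). ACE, ADRA2C, PDE2A, TGFB2, FST and ACVRL1 lost theirs in 9, 2, 7, 8, 3 and 4 of the 10 refits without 1 library.

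The largest falls among the named genes were smaller than the largest rises. VTCN1, an immune checkpoint ligand (chromosome 4, 103390547 to 103584847), fell by 2.98 ± 0.42, from 6.68 ± 0.55 in Sham to 3.71 ± 0.77 in CTEPH (SD, n = 5 each; adjusted p = 0.00163, limma with Benjamini-Hochberg). The receptor tyrosine kinase gene ROS1 fell by 2.32 ± 0.38, the ubiquitin ligase LNX1 by 2.25 ± 0.49, the mitochondrial carrier SLC25A45 by 2.25 ± 0.54, the calcium-dependent NADPH oxidase NOX5 by 2.24 ± 0.40 and NWD1 by 2.19 ± 0.58. FOXA3 fell by 2.10 ± 0.50, SSUH2 by 1.94 ± 0.41, the metalloreductase STEAP4 by 1.91 ± 0.31 and ASB14 by 1.91 ± 0.29, and MMP11 and KCND3 completed the 12. In each of them all 5 CTEPH libraries lay below every Sham library, which the naming rule requires of these 12 genes. LNX1, SLC25A45, NWD1 and FOXA3 lost their calls in 3, 6, 8 and 7 of the 10 refits without 1 library, and SLC25A45 also with voom on recovered counts (limma adjusted p = 0.0644, Benjamini-Hochberg).

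**Figure D3:**
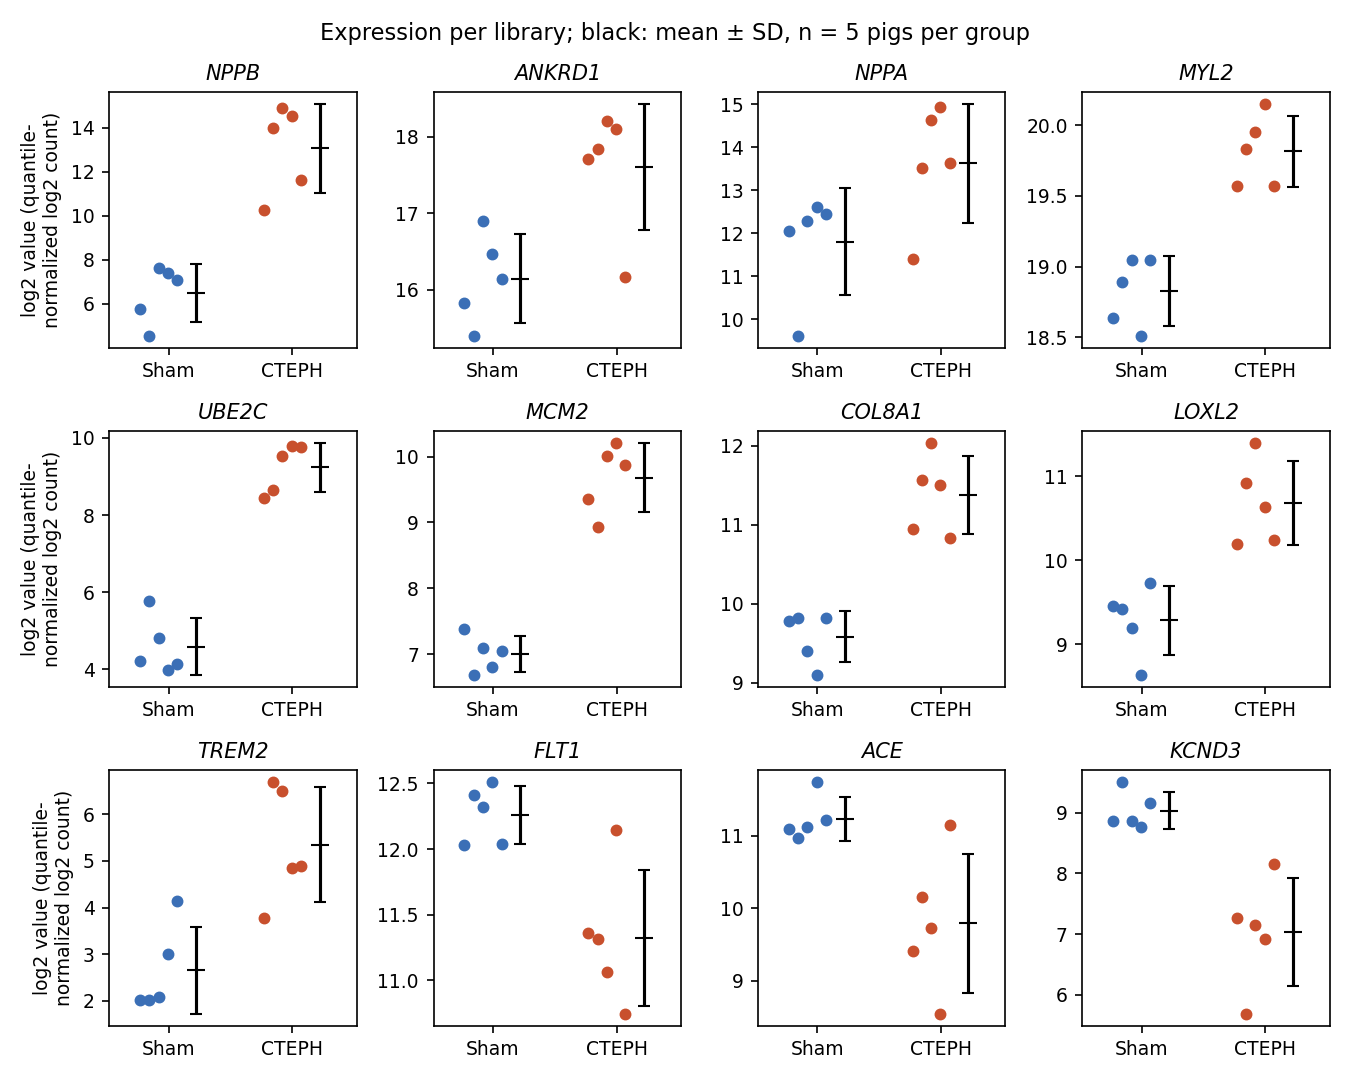
Log2 values (vertical, quantile-normalized) of 12 named genes in each Sham (blue) and CTEPH (red) library, 1 point per pig, with the mean and SD of 5 pigs in black. NPPB runs from 4.54 to 7.65 in Sham and from 10.26 to 14.92 in CTEPH. NPPA, ANKRD1, TREM2, FLT1 and ACE have 1 CTEPH library each within the Sham range.

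Markers of other cell types moved in few genes. DES (1.51 ± 0.32), which cardiomyocytes also express, and CNN1 (1.98 ± 0.47) rose among 19 smooth muscle and pericyte genes, of which 5 rose and 3 fell when adjusted over the list alone (limma, Benjamini-Hochberg). KRT8 (3.53 ± 0.85) rose among 5 mesothelial and epicardial genes, with 2 rising and 1 falling adjusted over the list alone, and DKK3 (2.22 ± 0.42) and KCNA5 rose among 11 atrial myocyte genes, with 5 rising and 2 falling adjusted over the list alone. CIDEA and PLIN4 fell by 1.22 ± 0.28 and 1.12 ± 0.27 among 14 adipocyte genes, the same count as adjusted over the list alone, and SOX10 and L1CAM by 1.09 ± 0.26 and 0.90 ± 0.21 among 9 Schwann cell and neuron genes, with 1 rising and 3 falling adjusted over the list alone. Camera adjusted p of these 5 lists were 0.263, 0.379, 0.0726, 0.460 and 0.0733 (Benjamini-Hochberg). By limma 0 of 25 immediate early genes, 0 of 30 cytosolic ribosomal protein genes and 0 of 21 muscle atrophy and proteolysis genes passed, with 3, 2 and 3 at an unadjusted p under 0.05, 0 adjusted over each list alone and camera adjusted p = 0.0558, 0.0664 and 0.897 (Benjamini-Hochberg). In the 10 refits without 1 library, the atrial myocyte, Schwann cell and neuron, immediate early and ribosomal lists were uncalled in 8, 8, 5 and 6. In the remaining refits these lists were called, with camera adjusted p down to 0.0134, 0.0359, 0.00117 and 1.6e-04 (Benjamini-Hochberg). The glycolysis, lymphatic endothelial and basement membrane lists were uncalled in 7, 7 and 9 of the 10 refits. Elsewhere they were called, with camera adjusted p down to 0.0219, 0.027 and 0.0208 (Benjamini-Hochberg). The lists of red blood cell, sex-linked and replication-dependent histone genes had 2 measured genes each, below the minimum of 3 for a list test, and 0 of their genes passed or had an unadjusted p under 0.05 by limma. CNN1, KRT8, CIDEA, PLIN4, SOX10 and L1CAM lost their calls in 6, 6, 5, 6, 5 and 6 of the 10 refits without 1 library, and SOX10 also with voom on recovered counts (limma adjusted p = 0.0560, Benjamini-Hochberg).

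Over the 40 tested lists, camera called 12, 8 higher and 4 lower in CTEPH, 0 held with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 2 lists in 1 direction, proliferation and neurohormonal, and 25 by its mixed test (Benjamini-Hochberg). Compared as levels per library, 10 of the 43 lists had an exact permutation p under 0.05 and 0 passed after adjustment, with a smallest adjusted p of 0.0683 (Benjamini-Hochberg). The proliferation list was at the smallest possible exact permutation p of 0.00794. Over 43 lists that p passes adjustment only where several lists reach it together, so the lack of passing lists does not count against a single list. For fatty acid oxidation and calcium handling the sign of the median (-0.02 and -0.02) was opposite to that of the mean (0.08 and 0.03), and for complement the median was 0.07 and the mean -0.06. In Sham library s6 the Y-linked genes EIF1AY and KDM5D had counts of 1 and 0, with KDM5D at a log2 value of 0.16, against log2 values of at least 10.69 for EIF1AY and 8.31 for KDM5D in every other library.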

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

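The tests of normalization, depth and macrophage content for the proliferation genes, of sex for library s6 and both tests for library s9 were chosen only after the results were seen; the split test and the depth test for s6 were written before. An earlier test of normalization by gene order, also written before, was dropped as void, because its reference genes were chosen for not differing between groups. In 166 groups of 5 libraries, 11 had a library whose distance to its nearest neighbour exceeded 0.71 of the group's range, and chance gives about 1 in 20.

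The rise of the proliferation genes in CTEPH was the largest shift of any list by median. By voom on recovered counts, which are free of quantile normalization, the 8 proliferation genes with such counts all rose, with a median log2 fold change of 3.34 against 3.30 from the deposited values, which argues against that normalization for them and leaves it open for the other 18. With log2 relative depth as a covariate the median log2 fold change was 2.96 and 25 of the 26 genes still rose, which argues against depth. More macrophages with an unchanged cycling share would raise both lists alike, but the macrophage and monocyte median was 0.43 with an SD of 0.766 over its genes. That SD does not measure the spread between pigs. Of the 4 called genes among 24, SPP1, LYZ and TREM2 rose by 2.30, 2.38 and 2.69 and LGMN by 0.85, while 20 were not called. The list median therefore does not settle the part of macrophages. A larger share of dividing cells in the CTEPH ventricle may explain the pattern, as a hypothesis drawn from these same libraries. Neither that share nor which cell type would divide was tested.

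Sham library s6 had almost no transcript of EIF1AY (1.07, a count of 1) and none counted of KDM5D (0.16, a count of 0). Its sex-linked list level was -8.52 against 0.90 to 1.34 in the other Sham libraries. Depth is no explanation, because s6 had a relative depth of 1.51, and 0 genes outside these 2 lay under 2 in s6 and at 8 or more in all other libraries. A female pig among males could give this pattern, but that stays open: the 2 genes at these levels, with 0 autosomal genes, are the observation itself. The sex of the pigs is not given in the sources used here, and a mislabelled library was not tested. NPPA was also low in s6, at 9.61 against 12.06 to 12.62 in the other Sham libraries.

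CTEPH library s9 lay nearest to Sham on the first component and had ANKRD1 at 16.17, against 17.70 to 18.21 in the other CTEPH libraries. Dilution with unaffected muscle would shrink all changes alike on the linear scale but unequally on the log2 scale used here. Unequal fractions therefore cannot decide on dilution. The proliferation genes of s9 stood at 1.13 of the way from the Sham mean to the mean of the other CTEPH libraries. The natriuretic and stretch genes of s9, the 14 of 16 with a group difference of at least 0.5 on the log2 scale, stood at 0.278. The difference was 0.851 (p = 1e-04, the smallest that 10000 permutations of list membership can give, and 1.7e-04 after Benjamini-Hochberg adjustment over 5 libraries). That test permutes genes within 1 library and takes them as independent, so its p does not measure the spread between pigs. The same test passed in s1, s3 and s4 with the opposite sign, at differences of -0.59 to -0.35, so these lists also shift unequally in other pigs and dilution stays open. Depth stays open too: the Sham libraries, 3 of them within 20% of the depth of s9, ranged over only 2.32 on that component, against a distance of 20.4 from s9 to the mean of the other CTEPH libraries, but within CTEPH the shallowest library, s9 (0.724), had the lowest score and the deepest, s4 (1.57), the highest. A difference in stage of disease was not tested.

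CTEPH library s1 stood apart in TESMIN, at 3.57 against 5.85 to 6.52 in the other CTEPH libraries. VTCN1 was higher in s1, at 5.03 against 3.0 to 3.57. DNAAF6 was at 0.16 in Sham library s8 against 2.01 to 2.62, a difference of at most 3 counts. COL3A1 was at 16.06 in Sham library s7 against 16.57 to 16.76. The endothelial list level was -0.018 in CTEPH library s4 against -0.24 to -0.19 in the other CTEPH libraries. KDM5D was at 8.31 in CTEPH library s5 against 8.94 to 9.18.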

How the results depend on the processing

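Relative depth as a covariate and voom on the recovered counts were chosen after the data were seen; the other alternatives were planned. Of 100 splits of the 10 libraries drawn from 126, the real one included, only the real split gave as many as 723 genes. The highest of the others gave 17. This argues against a chance split but does not exclude it, because 1 in 100 is the smallest share that the draw allows. The split test says nothing about any other factor that differs between the groups. Median centring (723 genes) and repeated quantile normalization (722) barely moved values that are already quantile-normalized and say nothing about stability, and the planned pseudocount was not run because the values are log2. The count was 588 without the intensity trend, 716 with robust variances, 682 with a 1.5-fold minimum, 756 with 1 surrogate variable (620 shared) and 688 with depth as covariate (638 shared). Dropping the lowest 25% of genes left 273 higher genes. Fewer genes were tested there, and not every call among those still tested held. Library weights gave 1269 genes, 722 higher and 547 lower, and the cause was not tested. Testing against a 1.5-fold change gave 127, 121 higher and 6 lower, since that test asks for a larger change. Leaving out each library gave 401 to 961 genes, 270 to 570 higher and 117 to 392 lower, and 25 or 26 proliferation genes rose each time. Without the lowest 25% of genes 17 of the 18 proliferation genes still tested rose, with a median of 2.52, and 20 of 26 passed the 1.5-fold test. Without s6, 72.5% of calls were higher, against 61.3% in all libraries. On 6763 genes with recovered counts, limma called 336 genes from the deposited values and voom 308, with 283 shared, and TREM2, CTHRC1, SLC25A45 and SOX10 lost their calls with voom.

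Lists called numbered 0 with an estimated correlation, 2 with fry and 10 to 16 without 1 library. In refits that each left out 1 library, 41 of 75 called named genes and 8 of 12 called lists kept their call. Named genes kept direction and side of the threshold in 2524 of their gene and setting pairs, were newly called in 94 and lost the call in 214. Exact permutation of the group labels for the named genes says nothing about stability, because they were chosen on the same values. List tests kept direction and side of the threshold in 623 list and setting pairs, were newly called in 21 and lost the call in 36. Signs turned in 13 pairs, all of uncalled genes near 0 or sex-linked: COL3A1 (0.056) and PLN (-0.0084) with library weights, MYH6 (-0.10) and PLN (-0.019) with 1 surrogate variable, and the rest without 1 library. Over those refits the ranges were -0.17 to 0.11 for COL3A1, -0.13 to 0.079 for ATP2A2, -0.053 to 0.38 for MYH6, -0.048 to 0.064 for PLN, -0.064 to 2.49 for EIF1AY and -0.34 to 2.08 for KDM5D. The cause was not tested. Depth limits genes with few counts, such as TESMIN.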

Other observations

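The genes and gene families below were chosen after their values were seen, and the family tests were run only then.

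E2F1, a transcription factor of S phase entry, rose by 3.54 ± 0.24 on the log2 scale and FOXM1, which drives mitotic genes, by 2.94 ± 0.44 (SE, n = 5 pigs per group; adjusted p = 2.2e-05 and 0.00222, limma with Benjamini-Hochberg), with all 5 CTEPH libraries above every Sham library. The cell cycle inhibitor CDKN1A rose too, by 1.99 ± 0.39, in 4 of 5 CTEPH libraries above every Sham library. Among 205 groups of genes that share a symbol stem and have at least 8 measured members, 2 were enriched for rises: 10 of 31 kinesins (KIF), of which 2 fell, and 6 of 10 genes of the MCM stem (one-sided Fisher's exact test, adjusted p = 8.2e-06 and 3.5e-05, Benjamini-Hochberg over 410 tests). Fisher's test takes genes as independent, which genes that rise together are not, so these adjusted p-values overstate the evidence. KIF20A and MCM2 are also on the proliferation list. Without the lowest 25% of genes, 5 kinesins rose, since only 5 of the 10 were still tested. Other called genes were the Wnt antagonist FRZB (3.95 ± 0.79), the TWEAK receptor TNFRSF12A (2.37 ± 0.51), the hyaluronan receptor CD44 (1.73 ± 0.34) and the S100 genes S100A6 (1.65 ± 0.36), S100A11 (1.34 ± 0.23) and S100A10 (0.91 ± 0.19).

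Of 10 measured ABCA lipid transporters 4 fell, the only symbol stem enriched for falls (one-sided Fisher's exact test, adjusted p = 0.00321, Benjamini-Hochberg over 410 tests): ABCA6 by 1.19 ± 0.20, ABCA8 by 1.16 ± 0.23, ABCA9 by 1.02 ± 0.22 and ABCA5 by 0.87 ± 0.17. ABCA5 (11018692 to 11152916) and ABCA6 (11225068 to 11369161) lie near each other on chromosome 12 of Sscrofa11.1, and reads shared between such related genes stay uncertain. ABCA8 and ABCA9 had no coordinates here. Related genes may not change independently, as Fisher's test assumes, so its adjusted p may overstate the evidence. The count of falling ABCA genes was 3 or 4 in each refit without 1 library and 0 when tested against a 1.5-fold change. ACACB, the mitochondrial acetyl-CoA carboxylase, fell by 1.02 ± 0.19, RNF207 by 1.11 ± 0.17, the ribosomal protein gene RPL3L by 0.88 ± 0.19 and the adenylyl cyclase ADCY6 by 0.81 ± 0.19, each with all 5 CTEPH libraries below every Sham library. ABCA9, RPL3L, ADCY6, S100A6 and TNFRSF12A lost their calls in 4, 2, 7, 5 and 3 of the 10 refits without 1 library, with adjusted p of up to 0.0704 (limma, Benjamini-Hochberg).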
